A study of Homo sapiens with 8 samples.

How the data were processed

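Gene expression was measured on 8 one-color Agilent arrays of samples labelled as NGP cells, an established human neuroblastoma line. Per the labels' protocols, cells received CFC1 cDNA or a mock construct by lentivirus and were selected with puromycin. Total RNA was labelled with Cyanine3. The labels put 4 arrays in the mock group and 4 in the CFC1 group and number them 1 to 4 within each. They do not say whether the 4 samples of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

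The deposited table holds 50739 rows per array, each a value on a logarithmic scale that was read as log2. Feature extraction, background treatment, scaling between arrays and the base of the logarithm are not given in the sources used here. The deposited log2 values lie between -13.0 and 9.81, and each probe is set against a baseline. At most 1 array per probe has an exact 0, and no probe has all 8 arrays above or all 8 below 0. Up to 7 of the 8 arrays lie below 0 beside an exact zero, as a median taken over 15 arrays, 7 of them not used here, would allow. The baseline is not stated. A value therefore gives differences between arrays for 1 probe and no level of expression, and correlations between arrays depend on that baseline. The array medians ran from -0.145 to 0.139. The table has no background or saturation flags, so a fold against a level that may lie near background is a fitted value and not a bound. The number of arrays limits the precision.

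After 140 control spots were left out, 50599 probes remained. Of these, 31993 had 1 gene symbol in the platform annotation, none had several, and 18606 had none in the table given and stayed unnamed. Symbols were updated through accession for 28419 probes, through symbol for 3072 and through an older synonym for 480, and 22 kept the name in the annotation. The mean of a gene's probes was taken as its value, because centred probes hold no level by which to choose one, and this gave 21524 genes. Of the 21524, 69 are counted but not named. Gene names and the order of neighbouring genes came from the RefSeq gene table of assembly GRCh38.p14. No coordinates are given because the build of the array annotation is not named.

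The arrays labelled CFC1 were compared with the mock arrays by limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, all 8 arrays, equal weights, no replicate block). Adjusted p-values are Benjamini-Hochberg values from limma, two-sided, with a threshold of 0.05. A change of at least 1 on the log2 scale was also counted. CFC1 itself was compared by an exact two-sided permutation test over the 70 arrangements of the arrays. The text names CFC1, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap, leaving out uncharacterised transcripts. From each gene list it names up to 4 members with the largest change. Genes named outside this rule were chosen after their values were seen, and the text says so. Lists, tests and this rule were set before the data were examined. The 33 gene lists were tested against all other genes with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Their p-values were adjusted over the 33 lists. Of the list genes, 19 were not analysed here.

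The model was tested on simulated data with the 21524 genes of the comparison of arrays labelled CFC1 with mock arrays, 200 of them changed. It recovered 64% of changes of 1 log2 unit and 43% of changes of 0.5 unit. Of the 1-unit changes in genes with a spread below the median, 100% were recovered, and 4 of 111 calls were unchanged genes. Far fewer genes changed in the simulation than the 57.9% called in the data. These shares therefore do not give the recovery or the false calls of the comparison itself. The test had first required a higher recovery of all 1-unit changes, and its criterion was changed to low-spread genes, false calls and bias after the 64% was seen. In an examination added after the data were seen, the order of genes along chromosomes 1 to 22 was tested in 507 runs of about 40 neighbouring genes against 1000 shuffled gene orders. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for it.

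The alternatives planned before the data were examined were the replicate number as a block, quantile normalization, centring each array on its median, array weights, a trend in the prior variance, unmoderated variances in a test of each gene with Benjamini-Hochberg adjustment, a fit over all probes, and leaving out each array in turn. Added after the data were seen were a fit without genes of shifted chromosome runs, arrays set to the E1A control spots, and values read as natural logarithms.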

Results

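The data comprise 8 arrays of total RNA labelled as NGP neuroblastoma cells, 4 as mock-infected cells and 4 as cells that express CFC1. CFC1 encodes Cryptic, a membrane-bound EGF-CFC co-receptor for Nodal and related ligands of the TGF-beta family. The comparison asks how CFC1 affects the transcript profile of this line. Values are log2 differences from an unstated baseline for each probe, and 21524 genes were tested. Differences are given as arrays labelled CFC1 minus mock arrays, with n = 4 in each group.

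The transduced gene was not higher in the arrays labelled CFC1. Its single probe averaged 0.416 ± 0.503 (SD, n = 4) in the mock arrays and -0.380 ± 0.335 (SD, n = 4) in the arrays labelled CFC1. Mock replicates 1 to 4 gave 0.474, 1.101, 0.116 and -0.027, and the arrays labelled CFC1 gave 0.055, -0.688, -0.593 and -0.296. The difference was -0.80 on the log2 scale (95% interval -1.44 to -0.15), with an adjusted p of 0.0398 in limma. The exact permutation test gave p = 0.057, where the smallest possible p is 0.029. The call was lost without mock replicate 1 (-0.777, adjusted p = 0.0848) or 2 (-0.568, 0.061), and without CFC1 replicate 2 (-0.694, 0.0994), 3 (-0.726, 0.0961) or 4 (-0.825, 0.0696). It was also lost under 4 of 9 other settings that can alter p. These were the replicate number as a block (adjusted p = 0.0761) and each gene's own unmoderated variance (adjusted p = 0.0662). The others were the fit over all probes (adjusted p = 0.0546) and arrays set to the E1A control spots (-0.719, adjusted p = 0.0722). Over these 17 alternatives the adjusted p ran from 0.0266 to 0.0994, and 8 kept the call. The position of the probe in the transcript was not determined, and a probe outside the transduced cDNA would not detect it. Whether the probe also detects CFC1B, a near-identical copy with no probe of its own, is unknown, so the value may be that of both genes. Because CFC1 was not higher in the second group, that group is called the arrays labelled CFC1 throughout. Every direction below rests on the labels, which these values neither bear out nor contradict.

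The profiles of the groups lay far apart. Of the 21524 genes, 12456 (57.9%) passed the threshold, with 6388 higher and 6068 lower in the arrays labelled CFC1. At least 2-fold differences were found for 4021 genes, 2091 higher and 1930 lower. Differences above 8-fold were found for 475 genes higher and 266 lower. In 12157 genes (56.5%) the groups did not overlap, where chance gives 2.9%. The first principal component held 79.1% of the variance and separated the groups. The median SD of a gene was 0.113 over the mock arrays and 0.106 over the arrays labelled CFC1. Over probes, the SD of the group mean was 0.922 for the mock arrays and 0.456 for the arrays labelled CFC1. Correlations over genes of the baseline-relative values ran from 0.894 to 0.904 within mock, from 0.633 to 0.67 within the arrays labelled CFC1, and from -0.015 to 0.032 between the groups, and genes are not independent replicates. If the deposited logarithm were natural rather than binary, all differences would be larger and 5906 genes would pass 2-fold. Quantile normalization moved the difference of 32 of the 146 named genes other than CFC1 by over 1.5 times, 31 of them with the direction kept. Examples are CYP26A1 (-4.29 to -7.60), ROBO2 (-3.22 to -5.59), FST (-1.57 to -3.08), NTN1 (7.20 to 4.77) and HLA-B (7.23 to 4.77).

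The 12 largest rises included cell-surface, cytoskeletal and antigen-processing genes. S100A10, an annexin A2-binding protein, was higher by 12.54 (SE 0.195), and TPM2, a tropomyosin, by 8.47 (SE 0.251). HLA-C and HLA-B, heavy chains of MHC class I, were higher by 9.32 (SE 0.151) and 7.23 (SE 0.133), and TAP1, a peptide transporter of the same pathway, by 7.83 (SE 0.438). HLA-B and HLA-C are similar enough in sequence that their separate values are uncertain, and the 3 probes of HLA-B ran from 3.27 to 9.40. NOTCH2, a receptor of the Notch pathway, was higher by 7.73 (SE 0.075) and GRB10, an adaptor of insulin receptor signalling, by 7.80 (SE 0.109). RHBDF2 (7.95), VTRNA1-3 (7.95), MGST2 (7.93) and PON2 (7.78) followed. ANXA2P1 (7.56) is a pseudogene of ANXA2, so its value is uncertain. All 12 passed with adjusted p-values of 2.09e-06 or less.

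The 12 largest falls included secreted factors, transcription factors and adhesion molecules. HGF, the ligand of the MET receptor, changed by -5.74 (SE 0.132), CRH, corticotropin-releasing hormone, by -5.41 (SE 0.383), and RELN, the extracellular matrix protein reelin, by -5.05 (SE 0.120). The transcription factors FOXF2, EPAS1 and SOX6 changed by -5.24, -4.72 and -4.62. The adhesion genes DSC2, CDH18 and PCDHA3 changed by -4.88, -4.81 and -4.61. LIX1 (-5.11), PRR16 (-4.92) and AVIL (-4.81) completed the group. Their adjusted p-values were 8.05e-06 or less. For the 12 rises the mock means lay from -12.59 to -7.30, and for the 12 falls from 4.53 to 6.14. The means of the arrays labelled CFC1 lay between -0.38 and 0.73 for all 24 genes, near the unstated baseline. A rise or fall here is thus a difference between the groups and does not show which group changed. The table gives no level, so how close the dimmer group of any of these 24 genes lay to background is unknown.

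**Figure D1:**
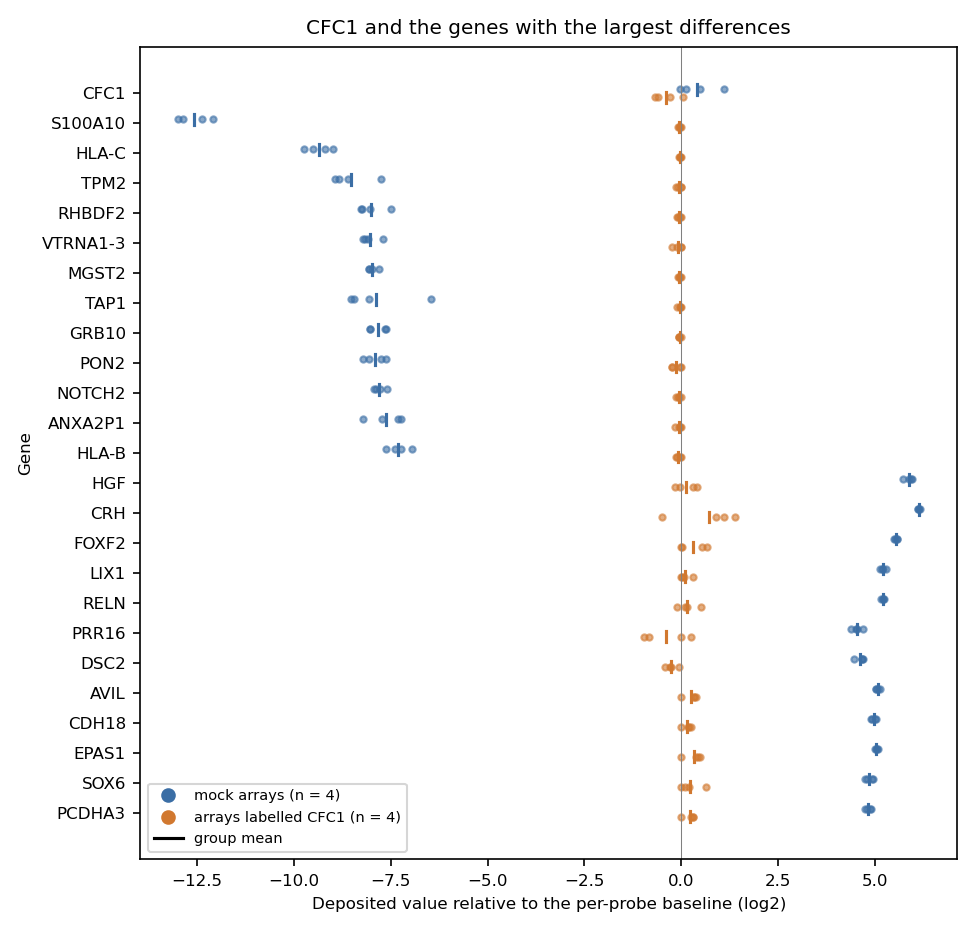
Values of CFC1 and of the 24 genes with the largest differences. The horizontal axis gives the deposited value (log2, relative to the baseline of each probe), points are single arrays, blue for 4 mock arrays and orange for 4 arrays labelled CFC1, and ticks are group means. The groups overlap for CFC1 (0.416 and -0.380 on average) and are apart for the others, from S100A10 (12.54) to HGF (-5.74).

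Among 14 measured targets of Nodal and activin signalling, 2 rose, 5 fell and 7 did not pass. FST, an activin-binding protein, changed by -1.57, SMAD7, an inhibitory SMAD, by -1.20, and CRIPTO, another EGF-CFC co-receptor, by -1.16. LEFTY1, a Nodal antagonist, rose by 0.92, although its groups overlapped and its call was lost with the replicate number as a block (adjusted p = 0.0682). The list did not stand apart from other genes (camera adjusted p = 0.292, median -0.25), and 7 members passed adjusted over the list alone. Among 21 components of the pathway, 5 rose and 11 fell (17 adjusted over the list alone, camera adjusted p = 0.25). The type II receptor TGFBR2 changed by -2.63 and TGFB3, a ligand, by -1.18, while INHBB, an inhibin subunit, rose by 2.20 and SMAD3, a signal transducer, by 1.22.

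Neuronal genes were lower in the arrays labelled CFC1. Of 21 measured members of the neuronal differentiation list, 4 rose and 15 fell, and 19 passed adjusted over the list alone. STMN2, a tubulin-binding protein of growing axons, changed by -3.92, NEFH, a neurofilament subunit, by -3.31, DCX, a microtubule protein of young neurons, by -2.42, and NRCAM, a cell adhesion molecule, by -1.93. The list median was -0.53 (camera adjusted p = 0.0132, and adjusted p = 0.397 with an estimated correlation), and after quantile normalization the median was -0.273 and the call was lost (adjusted p = 0.076). Stem cell genes were also lower: of 20 measured, 3 rose and 11 fell (14 adjusted over the list alone). PROM1, the surface antigen CD133, changed by -3.91, the transcription factors SALL4 and NANOG by -2.07 and -1.60, and the neurotrophin receptor NGFR by -1.79. That list had a median of -0.54 (camera adjusted p = 0.0174, and adjusted p = 0.3 with an estimated correlation).

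Cell cycle genes of G1 and S phase were higher. Of 19 measured, 15 rose and 2 fell (17 adjusted over the list alone). E2F1, a transcription factor of S phase entry, rose by 1.40, TYMS, thymidylate synthase, by 1.34, CDC25A, a phosphatase that activates cyclin-dependent kinases, by 1.26, and SLBP, which binds histone mRNA, by 1.09. The list median was 0.43 (camera adjusted p = 0.00845, and adjusted p = 0.565 with an estimated correlation). Of 20 genes of G2 and mitosis, 9 rose and 6 fell (15 adjusted over the list alone, camera adjusted p = 0.451), none by 2-fold. BUB1 rose by 0.82 and CCNB1 by 0.81, and BUB1B fell by 0.78. Of 21 genes of MYC and ribosome biogenesis, 12 rose and 6 fell (18 adjusted over the list alone, camera adjusted p = 0.251). The processing factor RRP9 rose by 1.56 and ODC1, ornithine decarboxylase, by 1.30, and CDK4, a G1 kinase, fell by 2.34.

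MHC class I genes moved most of all lists by their median. All 11 measured members rose (11 adjusted over the list alone), with a median of 2.87 and HLA-C at 9.32, and PSMB8, an immunoproteasome subunit, rose by 5.70. Camera gave an adjusted p of 1.17e-05, and adjusted p = 0.0581 with an estimated correlation. Of 14 cholesterol synthesis genes, 10 rose and 3 fell (13 adjusted over the list alone, median 0.65). SC5D, MVK and DHCR7, enzymes of the pathway, rose by 1.61, 1.07 and 1.03, and STARD4, a sterol carrier, fell by 1.35 (camera adjusted p = 0.0226, and adjusted p = 0.45 with an estimated correlation).

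Axon guidance and catecholamine genes were lower. Of 32 guidance genes, 5 rose and 20 fell (25 adjusted over the list alone), with a median of -1.0. The receptors EPHA4, ROBO2 and NRP1 changed by -3.63, -3.22 and -2.54, and the ligand NTN1 rose by 7.20 (camera adjusted p = 0.00449, and adjusted p = 0.301 with an estimated correlation). Of 16 genes of catecholamine synthesis, storage and secretion, 3 rose and 11 fell (14 adjusted over the list alone), with a median of -1.11. NPY, neuropeptide Y, changed by -3.66, SLC18A1, a vesicular monoamine transporter, by -3.02, DDC, which makes dopamine, by -2.51, and SCG2, a secretory granule protein, by -2.49 (camera adjusted p = 0.0174, and adjusted p = 0.565 with an estimated correlation). Of 14 adrenergic transcription factors, 4 rose and 9 fell (camera adjusted p = 0.125). TFAP2B changed by -3.86, SIX3 by -2.25, ISL1 by -2.18 and GATA2 by -1.66.

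In the other signalling lists, members moved in both directions and camera called none. Of 18 mesenchymal transcription factors, 4 rose and 6 fell (adjusted p = 0.935). NOTCH2, named above, and FOSL1 were higher by 7.73 and 2.09, and PRRX1 and TBX18 lower at -2.30 and -1.61. Of 27 mesenchymal and matrix genes, 7 rose and 14 fell (adjusted p = 0.251), with TWIST2 at 3.18 (mean of 3 probes from 1.12 to 6.82), VIM at 2.01, ZEB2 at -2.04 and COL3A1 at -1.88. Of 13 BMP targets, 5 rose and 6 fell (12 adjusted over the list alone, adjusted p = 0.811), with MSX1 at 4.34, NOG at 4.10 and SMAD6 at -1.59. Of 9 Notch targets, 4 rose and 2 fell (adjusted p = 0.292), with NOTCH3 at 6.42 and HES4 at 3.50. Of 11 WNT targets, 5 rose and 4 fell (adjusted p = 0.935), with SP5 at 4.26, DKK1 at -3.38 and LGR5 at -2.63. Of 9 retinoic acid targets, 1 rose and 6 fell, with CYP26A1 at -4.29, DHRS3 at -4.18 and RARB at -2.02. That list had an adjusted p of 0.0681, 0.0369 after quantile normalization and 0.0344 with arrays set to the E1A control spots. Of 18 immediate early and MAPK genes, 11 rose and 5 fell (adjusted p = 0.111), with ETV4 at 3.64, EGR3 at 3.38 and EGR2 at 2.94.

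Camera called none of the other stress, immune and metabolic lists. Each had called members in both directions, though rises far outnumbered falls for NF-kB, heat shock and hypoxia genes. Of 24 p53 targets, 13 rose and 9 fell (adjusted p = 0.4), with the death receptor TNFRSF10B at 4.91, GDF15 at 2.99, SPATA18 at -3.43 and TP53I3 at -2.17. Of 15 BCL2 family genes, 5 rose and 5 fell (adjusted p = 0.994), with BBC3 at 1.61 and HRK at -3.34. Of 21 interferon genes, 9 rose and 5 fell (adjusted p = 0.446), with HERC5 at 4.95, MX1 at 3.98, ISG15 at 3.77 and IFI44 at 3.72. Of 12 NF-kB and inflammation genes, 5 rose and 1 fell (adjusted p = 0.301), with CCL2 at 3.08. Of 17 hypoxia and glycolysis genes, 11 rose and 4 fell (adjusted p = 0.111), with HK2 at 1.51 and the angiogenic factor VEGFA at -1.77. Of 19 respiratory chain genes, 11 rose and 6 fell (adjusted p = 0.25), none by 2-fold, with UQCRC1 at 0.94. CYCS, of the same list, had probes called in opposite directions. Of 16 unfolded protein and integrated stress response genes, 5 rose and 7 fell (adjusted p = 0.892), and of 9 heat shock genes, 5 rose and 1 fell (adjusted p = 0.202), with BAG3 at 2.72.

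Markers of other cell types gave no list that camera called. Of 10 Schwann and glial markers, 1 rose and 4 fell (adjusted p = 0.4), with EGR2 at 2.94 and S100B at -1.35. Of 10 fibroblast and mural markers, 2 rose and 6 fell (adjusted p = 0.125), with RGS5 at -3.83 and PDGFRA at -2.78. Of 12 neural crest genes, 3 rose and 5 fell (adjusted p = 0.717), with TFAP2A at 2.14 and ETS1 at -1.80. Of 10 endothelial markers, 1 rose and 2 fell (adjusted p = 0.453), with ENG at 3.29 and KDR at -3.08. Of 12 epithelial markers, 3 rose and 4 fell (adjusted p = 0.818), with KRT19 at 2.84 and EPCAM at -2.86. Of 10 immune markers, CD14 rose by 1.16 and CD68 was lower at -0.42, and 1 passed adjusted over the list alone (adjusted p = 0.935). Of 38 named genes with several probes, 14 had probes apart by more than 1 log2 unit, so that their mean may describe no single probe. Besides HLA-B, TWIST2 and CYCS these included RARB (-3.31 to -0.13), S100B (-2.55 to -0.15), SLC18A1 (-4.12 to -1.92), TFAP2A (1.09 to 3.19), DDC (-3.34 to -1.68), GRB10 (7.16 to 8.44), TPM2 (7.97 to 8.98) and ZEB2 (-2.64 to -1.58). The neural crest gene PAX7 (-3.59 to 0.51) and the fibroblast and mural markers DCN (-2.1 to -0.17) and CSPG4 (-1.47 to -0.22) completed them. The call of CD68 was lost after quantile normalization (-0.26, adjusted p = 0.32), with arrays set to the E1A control spots, with unmoderated variances, in the fit over all probes, and without mock replicate 1, 3 or 4 or CFC1 replicate 1, 2 or 4 (-0.439 to -0.337). ESRP1 (0.98), 1 of the 3 epithelial markers that rose, lost its call with the replicate number as a block (adjusted p = 0.0676) and with unmoderated variances. The call was also lost without mock replicate 1, 2 or 3 or CFC1 replicate 3 (0.932 to 0.978). After quantile normalization ESRP1 stood at -0.116 (adjusted p = 0.891). FABP7 (-1.17), a Schwann and glial marker, lost its call with unmoderated variances and without any single array other than mock replicate 3 (-1.228 to -0.959), and DTX1, a Notch target, after quantile normalization (-0.448, adjusted p = 0.055). In 30 of the 33 lists the count adjusted over the list alone equalled that over all genes tested. Camera called 7 lists with the preset correlation and 0 with an estimated one, where 4 passed before adjustment. For MHC class I and stemness the estimated correlation (-0.081 and -0.014) lay below the preset 0.01. Correlation between genes therefore does not account for those 2 lost calls. The self-contained test fry called 28 lists. Median, mean and camera's direction did not share a sign for BMP targets, WNT targets, mesenchymal transcription factors, neural crest, immune and epithelial markers, the BCL2 family, interferon genes and the unfolded protein and integrated stress response.

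**Figure D2:**
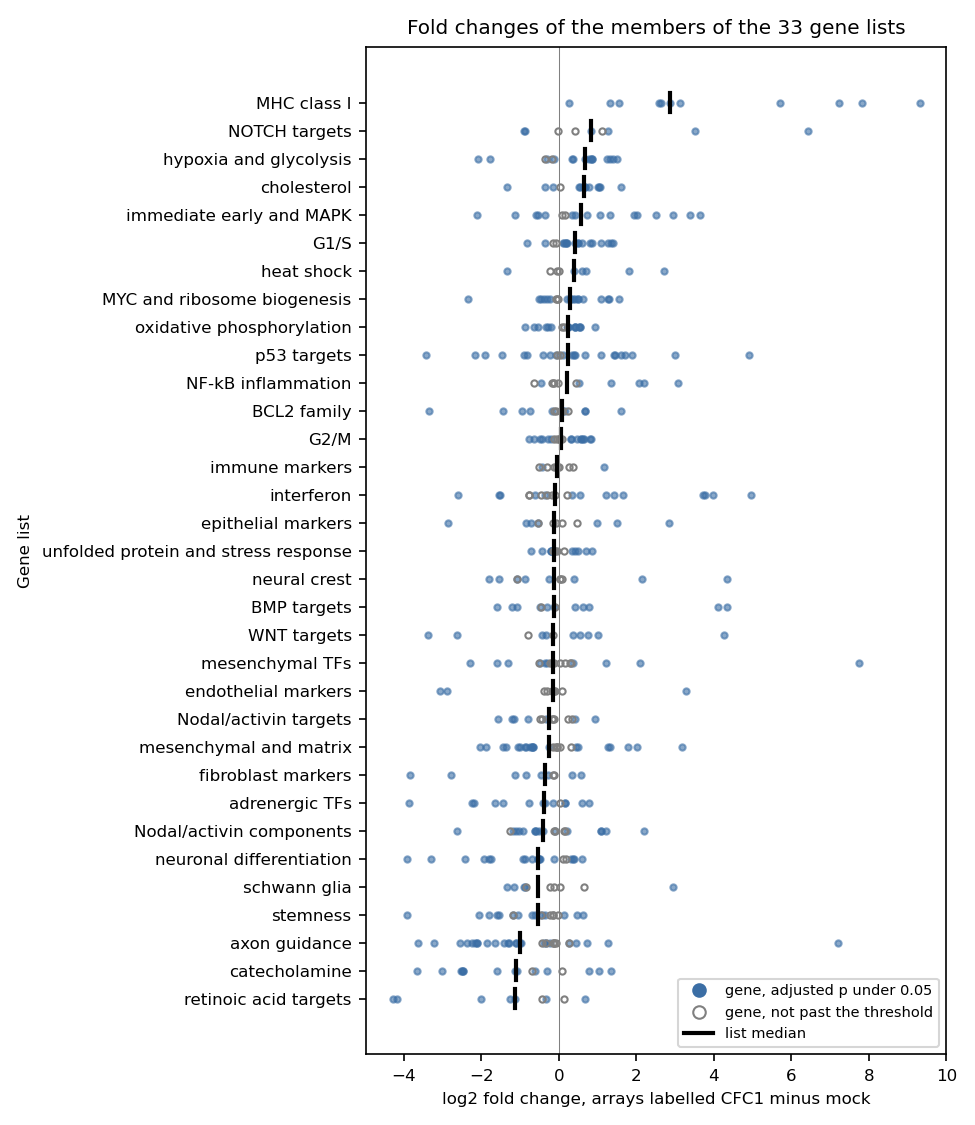
Log2 fold changes (horizontal axis, arrays labelled CFC1 minus mock arrays) of the measured members of each of the 33 gene lists (vertical axis). Blue points passed the adjusted threshold, open grey points did not, and black ticks are list medians, from -1.12 for retinoic acid targets to 2.87 for MHC class I.

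Differences followed the order of genes along chromosomes. NGP is known to carry extra copies of MYCN and of the part of chromosome 12 that holds CDK4 and MDM2. CDK4 fell by 2.34, and the genes discussed next were chosen after their values were seen. MDM2, an inhibitor of p53, fell by 1.92 (SE 0.029). In the block from TSPAN31 to ATP23 that holds CDK4, all 10 genes besides CDK4 were lower by at least 2-fold (median -2.66), and in the block from RAP1B to LGR5 that holds MDM2, 13 of the 20 genes besides MDM2 were (median -1.93). AVIL and LGR5, named above, belong to these blocks. The mock means of CDK4, AVIL and LGR5 were 2.36, 5.07 and 2.39. In the arrays labelled CFC1 they were 0.02, 0.26 and -0.24, near the unstated baseline. For these genes of chromosome 12 the mock arrays were thus the higher group. Without a level or a known baseline, the values do not give the copy number of either group. On chromosome 2, the neighbours of MYCN, NBAS and DDX1, were higher by 2.31 and 2.64, while MYCN itself differed by 0.16 (adjusted p = 0.0162).

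Over the autosomes, the variance of the medians of 507 runs of about 40 neighbouring genes was 9.87 times its mean in 1000 shuffled gene orders (permutation p = 0.001, the smallest these shuffles can give). Within groups, mock replicates 1 and 2 against 3 and 4 gave a ratio of 1.42 (permutation p = 0.001), and the same split of the arrays labelled CFC1 gave 1.25 (permutation p = 0.002). Between the groups 19 runs lay beyond every shuffled run, 14 above and 5 below, and within groups 0 did. Runs above lay on chromosome 19 (4 runs), 3, 11 and 16 (3 runs each) and 4, and those below included 2 on chromosome 12, 2 on chromosome 14 and 1 on chromosome 5. Without the genes of these runs, an alternative added after the data were seen, 11863 genes passed the threshold and 3686 differed by at least 2-fold.

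**Figure D3:**
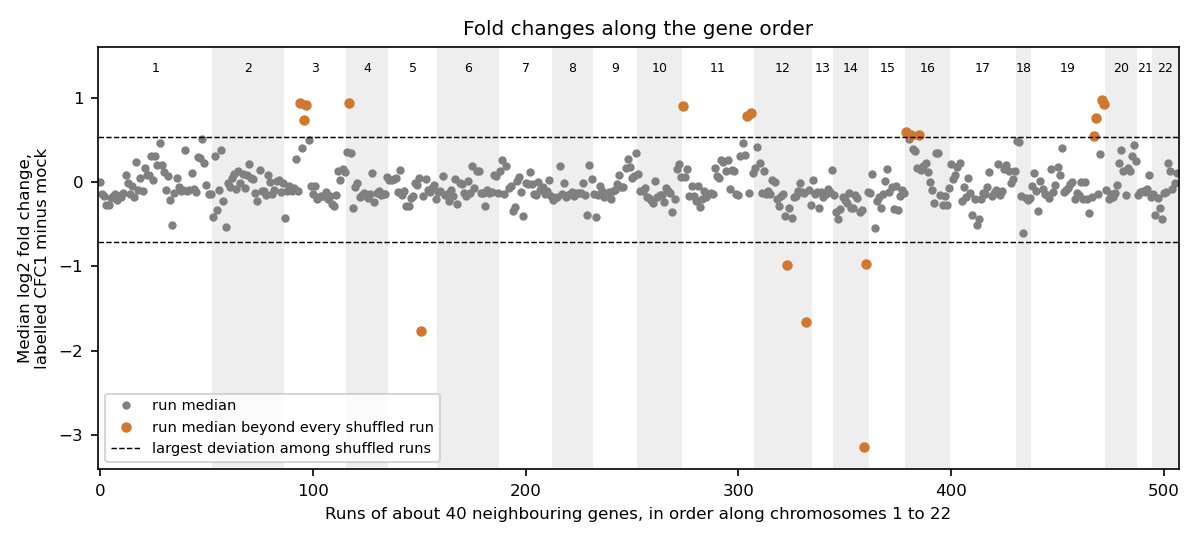
Median log2 fold change (vertical axis, arrays labelled CFC1 minus mock arrays) of each run of about 40 neighbouring genes in order along chromosomes 1 to 22 (horizontal axis). Orange points are the 19 runs beyond every shuffled run and dashed lines mark the largest deviation among shuffled runs; the lowest run, on chromosome 14, has a median of -3.14.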

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

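Among 147 named genes in 294 groups of 4 arrays, 21 (7.1%) had 1 array whose gap to the next, as a share of the group's range, exceeded the 95% critical value of Dixon's test, where chance gives about 5%. In the arrays labelled CFC1 this share was 0.898 for GRB10, 0.841 for AVIL, 0.839 for PCDHA3, 0.860 for TGFBR2, 0.848 for DCX, 0.890 for SALL4, 0.892 for ODC1, 0.898 for GNL3, 0.871 for HRK, 0.83 for SP5, 0.897 for HES4 and 0.867 for BAG3. In the mock arrays it was 0.833 for RELN, 0.864 for DSC2, 0.869 for COL3A1, 0.933 for NGFR, 0.905 for ETS1, 0.867 for UBE2C, 0.895 for DHRS3, 0.889 for ETV4 and 0.862 for EGR3. CFC1 replicate 3 was the separate array 6 times and no other array more than 4 times. Among these 21, the widest gap on the log2 scale was that of TGFBR2, at 1.06 in CFC1 replicate 1 against -0.29 to -0.10 in the other arrays of the group. NGFR, with the highest share, lay at 1.86 in mock replicate 1 against 1.82 in the others.

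The probes without a gene name were not part of the comparison of genes. Of 18606 such probes, 4135 passed the threshold in limma and 1949 differed by at least 2-fold, 645 higher and 1304 lower in the arrays labelled CFC1.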

How the results depend on the processing

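The fits without genes of shifted chromosome runs, with arrays set to the E1A control spots and with values read as natural logarithms were chosen after the data were seen. Counts of genes stayed within 1.5 times the reported ones under every alternative except the fit over all probes, which tests more rows and gave 21289 past the threshold (10123 higher, 11166 lower) and 7911 at least 2-fold (3651 higher, 4260 lower). Leaving out each array gave 12007 to 12198 genes and 3995 to 4030 at least 2-fold. Quantile normalization gave 11292 and 3579, of which 3022 were shared with the 4021. The share of genes past the threshold that were higher was 51.3% as reported, 48.8% with the replicate block, 55.7% after quantile normalization and 57.2% with arrays set to the E1A control spots. CFC1 kept its call under 8 of the 17 alternatives that can alter its p. Where the estimate can move, it was -0.944 to -0.568 when single arrays were left out, -0.889 after quantile normalization and -0.719 with arrays set to the E1A control spots. It was -0.796 with unmoderated variances and over all probes, where the call was lost, and the cause of the lost calls was not tested. With the replicate number as a block, 13200 genes passed (3992 at least 2-fold), and CFC1 (-0.796, adjusted p = 0.0761), LEFTY1 (0.0682) and ESRP1 (0.0676) lost their calls. In their deviations from the group means, arrays of the same number correlated at 0.074 to 0.199 and arrays of different numbers at -0.14 to 0.068. The rule used asks every same-number pair to exceed a set limit, which the lowest, 0.074, missed, so the numbers were not treated as pairs. Yet 8 of 8 arrays correlated best with their own number, a hint from the data and not the design. The second principal component (4.6% of the variance) also followed the numbers, positive in replicates 1 and 3 and negative in 2 and 4 of both groups. With an estimated correlation the lists of neuronal differentiation (0.397), stemness (0.3) and G1 and S phase (0.565) lost their calls, and after quantile normalization neuronal differentiation did (0.076), for which the cause was not tested. Fry, which compares no list with other genes, gave adjusted p-values of 5.32e-05 for Nodal and activin targets, 0.00102 for G2 and mitosis and 7.21e-06 for MYC and ribosome biogenesis, and turned the direction for mesenchymal transcription factors (1.4e-05), the BCL2 family (4.86e-05) and WNT targets (1e-05). Read as natural logarithms, which enlarges every value alike and alters no p, the medians were -0.786 for stemness and 0.618 for G1 and S phase, and 5906 genes reached 2-fold. ESRP1 turned to -0.116 after quantile normalization. The filter on dim probes and the choice of the probe with the highest mean were not run, because centred values hold no level, and signal over background is unknown. The mean of a gene's probes, planned as an alternative, was the setting used.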

Other observations

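The following families were chosen after their values were seen and were not tested for enrichment. Over all genes, 57.9% passed the threshold. Of 15 protocadherin alpha genes, 14 fell (median -2.75) and 1 rose, of 18 beta genes 12 fell and 2 rose (median -1.58), and of 17 gamma genes 13 fell and 0 rose (median -1.89). All 37 SNORD113 and SNORD114 genes, small nucleolar RNAs of an imprinted cluster on chromosome 14, fell (median -3.38). Of 13 metallothioneins, which bind zinc and copper, 9 rose and 1 fell (median 1.18). Of 9 HOXD genes, 1 rose and 6 fell (median -1.05), and of 6 GAGE and XAGE genes, 5 rose and 0 fell (median 3.03). Collagens and ZNF genes went both ways, with 5 of 44 collagens higher and 24 lower (median -0.67), and 222 of 520 ZNF genes higher and 155 lower (median 0.06, and 0.16 after quantile normalization and 0.14 with arrays set to the E1A control spots). At least 2-fold, 93 ZNF genes were higher and 15 lower. Each of the 4 runs above on chromosome 19 starts or ends at a ZNF gene. The medians kept their sign after quantile normalization, with arrays centred on their medians and with arrays set to the E1A control spots. Members of the protocadherin, metallothionein and SNORD families resemble each other in sequence, so single values are uncertain.

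The tests of baselines and of array scaling below, and of exchanged names, were chosen after the results they bear on were seen. The first pattern is the number of genes that differ. Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many genes (12456), and the highest other split gave 3. That argues against a chance division of these 8 arrays. Every other split mixes the 2 groups, so the splits cannot tell whether chance differences between cultures set the groups apart. Separate baselines for the groups would have left about 2660 probes with an exact 0 in both groups, and 0 were found. A constant offset in array scaling is argued against by the E1A control spots, which detect spiked-in RNA and differed by -0.073 (range -0.198 to -0.053). These spots cannot test a difference in spread or one that varies with intensity. Quantile normalization, which gives all arrays 1 distribution of baseline-relative values and so evens out spread, kept 3022 of the 4021 genes at 2-fold. Because these values hold no level, it cannot test a difference that varies with intensity either. What stays open is that the groups may hold cells of different chromosome copy number, for which the ratio of 9.87 over neighbouring genes was as this hypothesis predicts, but since ratios of 1.42 and 1.25 within groups also passed their test, the further condition that the ratio and the runs beyond shuffles exceed those within groups was added after the result was seen. Local co-regulation could account for some runs, such as the protocadherins and the SNORD cluster, and another line, a subclone or a mislabelled set of samples were not separated. The genes around CDK4 and MDM2 fell together: all 10 besides CDK4 and 13 of 20 besides MDM2 by at least 2-fold. Over all 21524 genes, 1930 passed the threshold and were lower by at least 2-fold. These blocks and their ends were chosen after their values were seen, so the counts do not test a copy number difference. Around MYCN the values went apart, with NBAS at 2.31, DDX1 at 2.64 and MYCN at 0.16. The difference that the design names, expression of CFC1, stays untested as a source for any single gene, those of these blocks included.

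The second pattern is CFC1, which was -0.80 in the arrays labelled CFC1. An exchange of the names of the groups cannot be told apart from no such exchange, since the 95% interval of the difference, -1.44 to -0.15, includes 2-fold. The test also presumes a probe within the transduced cDNA, which is unknown, so it could not decide the question. Such an exchange would turn every direction in the text. Whether the 1 probe of CFC1 lies outside the transduced cDNA cannot be told apart either, because its place in the transcript was not tested. If it does, the probe may report only the endogenous gene. No biological explanation was tested.

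The highest value of the table, 9.81, came from 1 probe in CFC1 replicate 4, where the other 7 arrays lay between -0.38 and 0.26.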
